A study of Mus musculus with 6 samples.

How the data were processed

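Total RNA from immortalized monoclonal lines of mouse mesenchymal stem cells was sequenced after depletion of ribosomal RNA, per the labels' protocols. The 6 groups were Dicer wild-type (WT) cells, Dicer knockout (KO) cells, and WT cells that carried either the vector alone or a vector for Pbx3, Sox9 or Tead4. The labels call the cells both mesenchymal stem cells and fibroblasts. Libraries were strand-specific and read from a single end, per the labels' protocols. Each genotype is a single clone, so genotype and clone cannot be told apart.

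Reads were aligned with Bowtie2 to mm9 and compared with DESeq 1.10.1, per the submitters' processing notes. The 8 deposited tables give, for 4 comparisons, exonic and intronic reads per gene separately. The signal columns hold read counts that the authors divided by DESeq size factors and averaged over the libraries of each group. The fold change column is the ratio of the treated mean to the control mean, as the authors deposited it. The log2 column is the log2 of that ratio with no pseudocount, as deposited by the authors. The p-value columns come from the authors' negative binomial test, per the file headers and the submitters' notes. The gene annotation, the way exonic and intronic reads were assigned, the use of strand in counting, the handling of reads shared by paralogs or overlapping genes, and the kind of RNA that the tables leave out by name are not given in the sources used here. None of the columns used for values was left without a group (0 unmapped).

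The labels list 1 sample per group, yet every deposited group mean was a whole-number combination of 2 steps, as the mean of 2 libraries would be. Whole reads of both libraries were recovered with a unique solution for 100% of 23227 genes in each exonic table and of 23231 genes in each intronic table, at a tolerance of 1e-09. The recovery was tested on simulated data and returned every read of 5000 simulated genes. The vector reads recovered from the 3 factor tables differed for 0 genes. Library 1 is the library with the larger size factor in each group, separately for exonic and intronic tables, and these numbers pair nothing between groups or kinds of reads; by the direction of their difference, exonic KO library 1 goes with intronic KO library 2. Whether the 2 libraries are separate cultures is not stated, so the p values measure only the spread between these libraries, which can be technical. Exonic depth ranged from 6130267 to 23501655 reads over the 12 libraries and intronic depth from 3156973 to 10205497 reads. The median chi-square of the difference between the 2 libraries of a group was 1.34 to 10.1, where counting error alone would give less than 1. Intervals and floors cover counting error only, and a floor is 3 reads over the group.

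The size rule called a gene at least 2-fold apart from the log2 ratio of the group means with a pseudocount of 1, among genes with a mean of at least 50 normalised counts. This rule, the named genes, the 33 gene lists, the microRNA seeds and the alternatives other than those listed as added were fixed before the data were examined. The test across genes was added after the data were seen: limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2 of the normalised counts plus 1, 2 libraries against 2, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design named a test for counts where the tables give raw counts of each library. The tables give group means of normalised counts instead, so that test was not run, although the recovered reads would have allowed one; limma on the recovered values took its place. In simulations of 200 changed genes per table, limma recovered, of 100 genes given a log2 change of 1, 84 for Dicer KO, 69 for Pbx3, 78 for Sox9 and 95 for Tead4 in exonic reads, with 1.08% to 2.99% false calls. In intronic reads it recovered 85, 76, 88 and 92 of 100, with 7.54%, 1.70%, 7.84% and 3.52% false calls, so for Dicer KO and Sox9 above the 5% aimed at. The simulated genes varied independently, without the difference between libraries that the real genes share, so these rates need not hold for the real libraries. Of the real genes at least 2-fold apart in exonic reads, 1016 of 1336 passed limma for Dicer KO and 1 of 95 for Pbx3. For Sox9 these were 53 of 241 and for Tead4 14 of 318. A gene that did not pass is therefore not shown to be unchanged. Values with ± are limma log2 fold changes with their standard error, from 2 libraries per group. Exonic and intronic log2 values of the same library were also subtracted and tested with limma; the tables do not pair exonic with intronic libraries, so they were paired by the direction in which the 2 libraries of a group differ. A list was described by the median log2 fold change of its measured members and the percentile of that median among 10000 random lists matched in 20 bins of mean expression. The minimum takes the mean over both groups, so a gene near 0 in 1 group can enter through the other. Such genes move the median of a list toward the group where they are high. Seed sites were 7-mers of microRNA positions 2 to 8 in annotated 3′ untranslated regions, with random lists matched also in 5 bins of region length.

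The reference at hand was GENCODE M21 on GRCm38, which is another build than the tables use. It served for names, 3′ sequences, GC content, length and exon counts, and no coordinates are given. Of 27794 symbols in the tables, 18666 matched directly, 2480 matched by a synonym and 6648 did not match. Seeds were searched in 9265 genes. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

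Named genes followed a rule. In each comparison these are the targeted gene, the 10 genes with the highest and the 10 with the lowest exonic log2 fold change at a mean of at least 200, and the 5 highest and 5 lowest by intronic change at a mean of at least 200. For Dicer KO, the 5 highest and 5 lowest differences of exonic and intronic change were added. Of each described list, up to 4 members with the largest exonic change were taken. Dicer1, Pbx3, Sox9 and Tead4 were read in every comparison, and symbols of small non-coding RNAs were left out. Genes outside the rule are named as chosen after their values were seen. The alternatives fixed in advance were a pseudocount of 8, no minimum or a minimum of 200, log2 values centred on their median, columns rescaled to the same total, the authors' adjusted p at 0.1, an exact binomial test of the summed reads, random lists without matching on expression, and 8-mer sites. The alternatives chosen after seeing the data were limma, leaving out each library in turn, a term for library order and a joint fit of the 8 transfected libraries. Where a library is left out, the lone library of its group is assumed to vary like the other group.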

Results

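Total RNA was sequenced from immortalized clonal lines of mouse mesenchymal stem cells, which the labels also call fibroblasts. The 6 groups were Dicer WT, Dicer KO, and WT cells with vector alone, Pbx3, Sox9 or Tead4, each with 2 recovered libraries. Exonic reads numbered 23217547 and 18517189 in the Dicer WT libraries, 23501655 and 20712173 in Dicer KO, and 11011360 and 8580445 in vector. They numbered 10831047 and 9374739 in Pbx3, 7767701 and 6130267 in Sox9, and 10877587 and 8669890 in Tead4. Intronic reads, which come mostly from unspliced RNA, made up 31.4% of gene reads in Dicer WT, 29.9% in Dicer KO, 29.1% in vector, 28.7% in Pbx3, 33.1% in Sox9 and 29.6% in Tead4. Changes are limma log2 fold changes with their standard error, from 2 libraries per group, and "rose", "fell" and "changed" are kept for genes with a limma adjusted p under 0.05.

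The targeted genes were read first. Pbx3, a homeodomain transcription factor, rose by 7.04 ± 0.21 in exonic reads of Pbx3 cells (limma adjusted p = 0.0013), from 483 reads over both vector libraries to 65427. Tead4, a DNA-binding partner of YAP, rose by 7.17 ± 0.18 in Tead4 cells (limma adjusted p = 0.000284), from 38.8 and 40.7 to 6866 and 5050 normalised counts. Sox9, the master regulator of cartilage cells, was 1.29 ± 0.39 higher in Sox9 cells, from 116 and 47.5 to 179 and 186, and did not pass (limma adjusted p = 0.272). Its intronic reads numbered 7 in vector and 42 in Sox9 cells over both libraries (the authors' adjusted p = 0.0177). Dicer1 was lower in Dicer KO cells, at −0.46 ± 0.14 (limma adjusted p = 0.0859), with 1407 and 1344 normalised counts in WT and 935 and 1067 in KO. Totals over the gene cannot show whether a deleted part is missing, so they do not check the knockout. In the cells given another factor, none of the 4 genes passed limma where it was measured. The largest of these limma values was Sox9 at 0.62 ± 0.51 under Tead4. Tead4 under Sox9 lay below the minimum mean and was not tested with limma. Its log2 fold change from the authors was 0.697 in exonic and 0.749 in intronic reads. In Dicer KO cells, Tead4 rose by 2.24 ± 0.51 (limma adjusted p = 0.0415) and Pbx3 by 0.83 ± 0.15 (limma adjusted p = 0.0232), while Sox9 stood at −0.81 ± 1.19.

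**Figure D1:**
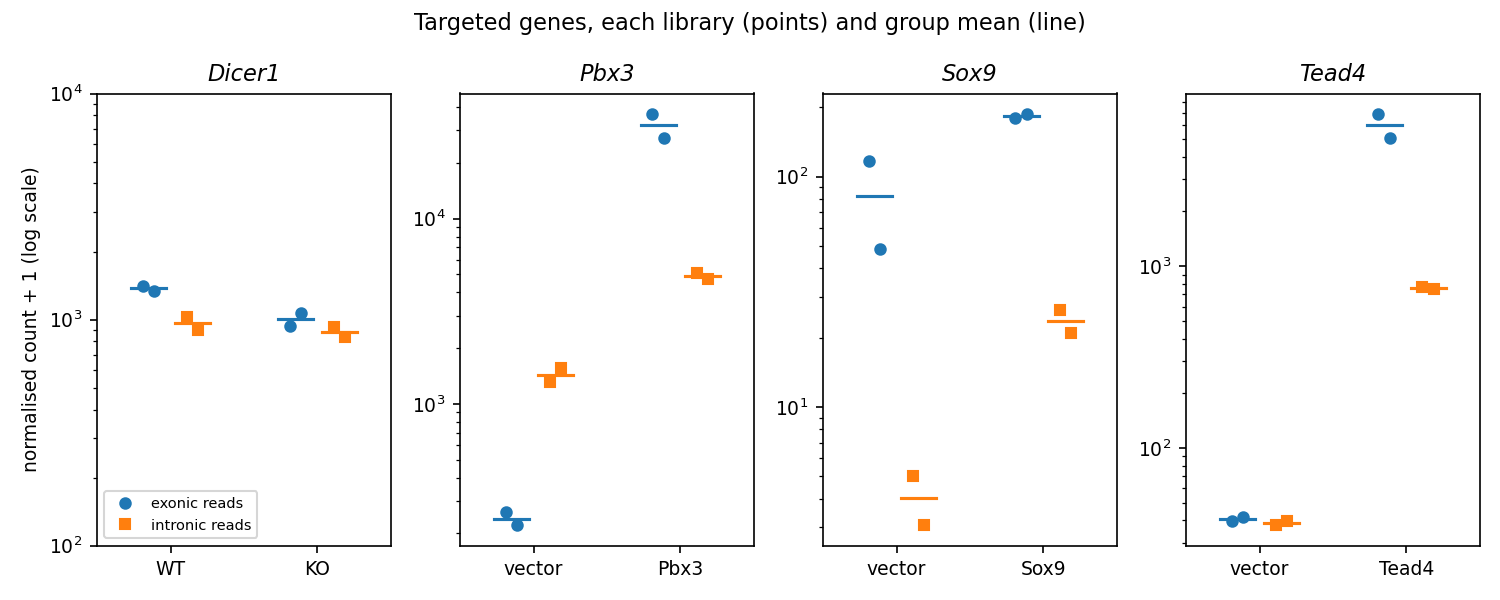
Normalised counts plus 1 (log axis) of Dicer1, Pbx3, Sox9 and Tead4 in control and treated groups, with exonic reads as circles and intronic reads as squares; each point is a library and each line a group mean of 2 libraries. Pbx3 and Tead4 lie above vector in both kinds of reads, and in exonic reads Sox9 and Dicer1 differ less than these.

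The 2 libraries of a group differed along genes shared by all 6 groups. Taken in the same order along these genes, cholesterol synthesis genes differed between libraries by a median of −1.51 to −0.46 in the 6 groups, osteoblast markers by −0.84 to −0.46, Wnt pathway genes by −0.67 to −0.14, adipocyte markers by −0.61 to −0.13 and stromal markers by −0.35 to −0.03. Cell cycle genes, at 0.02 to 0.24, and ribosomal protein genes, at 0.08 to 0.20, went the other way in all 6 groups. Single genes named below also differed between the libraries of all 6 groups. Edn1 did so by 0.36 to 2.21, Ctgf by 0.62 to 3.68 and Hbegf by 0.16 to 2.71. Opposite to these stood Islr, at −2.93 to −1.04, and Adamts9, at −2.97 to −1.13.

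The comparison of Dicer KO with Dicer WT cells asks which transcripts differ where Dicer, the enzyme that cuts microRNA precursors, is deleted. The fetal RNA-binding proteins Igf2bp3, Igf2bp1 and Igf2bp2, textbook targets of let-7 microRNAs, rose in exonic reads by 9.0 ± 0.52, 5.98 ± 0.16 and 5.19 ± 0.55. Igf2bp3 and Igf2bp2 also rose in intronic reads, by 6.98 ± 0.23 and 4.90 ± 0.26. For Igf2bp1 the authors' intronic log2 fold change was 4.866 (the authors' adjusted p = 1.27e-34). Of 25 measured let-7 targets and oncofetal genes, 16 rose and 9 did not pass limma, with 19 higher adjusted over the list alone. The list median of 1.12 lay at percentile 100 of random lists, against 0.27 at percentile 99.5 in intronic reads. Nr6a1, a nuclear receptor of early development, belonged to this list and rose by 4.0 ± 0.21.

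Genes of the interferon response rose in Dicer KO cells. Of 30 measured members, 21 rose, Tap1, the peptide transporter of antigen presentation, fell by 0.89, and 8 did not pass limma, with 26 higher and 2 lower adjusted over the list alone; Tap1 and Ifit2, the lower pair, were named after their values were seen. The antiviral genes Rsad2, Oas1a, Trim30a and Oasl2 rose by 7.39 ± 0.50, 5.13 ± 0.72, 3.87 ± 0.42 and 3.72 ± 0.37, and the list median was 1.72 at percentile 100. Of 15 inflammatory and NF-kB genes, Ccl2, Cxcl1, Vcam1, Csf1 and C3 rose (5, with 8 adjusted over the list alone), the chemokines Ccl2 and Cxcl1 by 2.31 ± 0.35 and 1.85 ± 0.22; Csf1 and C3 were chosen after their values were seen. Of 26 genes of the unfolded protein and integrated stress response, 12 rose, the chaperone Hsp90b1 fell by 0.76 and 13 did not pass limma, with 17 higher and 3 lower adjusted over the list alone. Hsp90b1, Pdia4 and Sdf2l1, the 3 lower members, were chosen after their values were seen. The cystine transporter Slc7a11 rose by 3.61 ± 0.23 and the glutathione-degrading enzyme Chac1 by 2.64 ± 0.19. The hormone Fgf21 rose by 5.94 ± 0.80 from 2 reads in WT, a ratio with a 95% counting interval of 29.1 to 885. Of 21 glycolysis and hypoxia genes, Pfkp, Aldoa, Pgk1, Pgam1 and Ero1l rose (5, with 9 higher adjusted over the list alone and 1, Pdk1, lower); Ero1l and Pfkp, an oxidase of the endoplasmic reticulum and a phosphofructokinase, rose by 2.42 ± 0.19 and 2.03 ± 0.17, and Pgk1, Pgam1 and Pdk1 were chosen after their values were seen.

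Several surface and secreted proteins were among the genes with the highest exonic change in Dicer KO cells. Mal, a membrane proteolipid, had 0 reads in WT and 1044 in KO, which makes it at least 331-fold higher at a floor of 3 reads over the group. The prolactin receptor Prlr rose by 6.12 ± 0.33, the orphan receptor Gpr141 by 5.60 ± 0.28 and the adhesion molecule Cadm1 by 5.08 ± 0.14. Kng1, a kininogen, rose by 5.40 ± 0.53, and reads that it shares with its paralog Kng2 cannot be told apart here. In intronic reads the phosphodiesterase Pde10a rose by 5.77 ± 0.40.

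Lists of matrix, bone, cartilage and contractile genes had low medians in Dicer KO cells. Of 34 matrix and remodelling genes, 12 fell and 22 did not pass limma, with 15 lower adjusted over the list alone; Fbln5, an elastic fibre protein, fell, at −5.31 ± 0.50, and so did the gelatinase Mmp2 at −5.10 ± 0.22 and the matrix proteins Aspn, at −5.09 ± 0.63, and Tnc. Of 12 osteoblast markers, 7 fell, with 8 lower adjusted over the list alone. They include Pth1r, the receptor of parathyroid hormone, at −5.66 ± 0.39, Sp7, which drives bone formation, at −5.38 ± 0.73, and Omd and Msx2 at −4.97 ± 0.73 and −3.96 ± 0.37. Of 11 SOX9 and cartilage genes, Col10a1, Col2a1, Col27a1 and Sox8 fell (4, with 7 lower adjusted over the list alone), the collagens at −5.99 ± 0.51, −4.12 ± 0.41 and −3.83 ± 0.28; Sox8 was chosen after its values were seen. Of 14 muscle and myofibroblast markers, 7 fell, 1 rose and 6 did not pass limma, with 9 lower and 1 higher adjusted over the list alone: the contractile genes Actg2, Cnn1 and Myl9 fell, at −7.42 ± 0.57, −5.86 ± 0.44 and −3.64 ± 0.19, while Tnnc1, a troponin, rose by 2.69 ± 0.55. The list medians were, in that order, −0.77, −1.54, −1.26 and −1.97, each at percentile 0. Tnnc1 and Omd did not pass the authors' test, with the authors' adjusted p at 0.147 and 0.128. The osteoblast list is among those that differed between the 2 libraries of every group. The muscle and myofibroblast list did not go the same way in all 6 groups. Between the 2 libraries it differed by 0.677 in Dicer WT and 0.658 in Dicer KO, beside −0.666 and −0.524 for osteoblast markers.

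Of 19 stromal markers, 5 fell, 2 rose and 12 did not pass limma in Dicer KO cells, with the same counts adjusted over the list alone; the adhesion molecule Mcam and the calcium-binding protein S100a4 fell, at −3.46 ± 0.28 and −2.46 ± 0.23, while Vcam1 and Twist2 rose by 1.55 ± 0.14 and 1.47 ± 0.28. The other members that fell, Ly6a, Twist1 and Nes, were chosen after their values were seen. Of 10 adipocyte markers, Fabp4, a fatty acid carrier, fell by 4.56 ± 0.16 and the lipase Pnpla2 rose by 1.06 ± 0.25, with the same 1 and 1 adjusted over the list alone, and 8 did not pass limma. Of 28 p53 targets, 10 fell and 18 did not pass limma, with 14 lower adjusted over the list alone; Eda2r, Trp53inp1 and Dcxr fell, at −2.04 ± 0.31, −1.86 ± 0.26 and −1.80 ± 0.23, and the list median was −0.57 at percentile 0. Of 38 ribosomal protein genes, 8 fell, also adjusted over the list alone, Rpsa most at −1.02 ± 0.14, with a median of −0.22 at percentile 0.11. The genes with the lowest exonic change included Plce1, a phospholipase, at −8.93 ± 0.39, Fstl3, which binds activin, at −7.94 ± 0.66, Tnn, a tenascin, at −7.48 ± 0.52, the receptor Ephb2 at −6.87 ± 0.24, Islr at −6.80 ± 1.15, Tnfrsf11b, the osteoprotegerin gene, at −6.66 ± 0.87, Khdrbs3 at −6.51 ± 0.67, Cap2 at −6.49 ± 0.49 and the zinc finger gene Zfp521 at −6.17 ± 0.52. The cholesterol synthesis list, with a median of −0.89 at percentile 0, had 0 of 20 members passing limma, 0 at an unadjusted p under 0.05, 0 in the authors' test and 0 adjusted over the list alone. The stromal, adipocyte, ribosomal protein and cholesterol lists are among those that differed between the 2 libraries of every group.

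Of 29 TEAD-YAP targets, 3 rose and 6 fell in Dicer KO cells, with 3 higher and 7 lower adjusted over the list alone. Edn1, a vasoactive peptide, fell by 3.73 ± 0.83 (the authors' adjusted p = 0.281) and Ccdc80 by 2.36 ± 0.28 (the authors' adjusted p = 0.00668). Between its 2 libraries Edn1 differed by 2.206 in Dicer WT and 1.465 in Dicer KO. The members that rose, Gadd45a, Dock5 and Wwc1, were chosen after their values were seen. Of 25 miR-29 targets, 7 rose and 4 fell, with 10 higher and 7 lower adjusted over the list alone; the basement membrane collagen Col4a1 rose by 2.27 ± 0.19 and the bone collagen Col1a1 fell by 2.31 ± 0.18. Col1a2, Col3a1 and Col6a3, which also fell, were chosen after their values were seen. The miR-29 median of 0.13, at percentile 78.1, and mean of −0.00 differ in sign, and the median was 0.28 at percentile 97.7 with a minimum mean of 200. Of 19 genes of the small RNA pathway, Tnrc6a, Eif2c2 and Tnrc6b, which code for proteins of the silencing complex, rose by 1.44 ± 0.12, 1.22 ± 0.15 and 0.93 ± 0.21; Tarbp2 was the other of the 4 that rose (5 higher and 1 lower adjusted over the list alone), and it, Adar and Ddx6, the further pair, were chosen after their values were seen. Of 17 Wnt pathway genes, 3 rose and 2 fell (4 and 3 adjusted over the list alone), with Wnt4 at 3.62 ± 0.54, Lgr6 at 3.41 ± 0.49 and Rspo2 at −3.56 ± 0.50; Sfrp4, Wnt5a and Rspo3 were chosen after their values were seen. Of 20 TGF-beta and BMP responsive genes, 3 rose and 5 fell (3 and 6 adjusted over the list alone), with Tgfbi at 1.99 ± 0.42, Id4 at −4.18 ± 0.92 and Bambi at −2.44 ± 0.26; Smad7, Id2, Id3, Tgfb2 and Bmp4, the others that changed, were chosen after their values were seen. Id4 did not pass the authors' test (the authors' adjusted p = 0.202). The Wnt list is among those that differed between the 2 libraries of every group.

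By size, 1336 of 10706 genes were at least 2-fold apart between Dicer KO and Dicer WT in exonic reads, 628 higher and 708 lower; in 1291 of them the libraries of the groups did not overlap. The share of all genes without overlap was 63.3%, where libraries that differ only at random would give 33.3%. The 2 libraries of every group differed along shared genes, so 33.3% is not a chance value for unchanged groups here or in the other comparisons. limma called 1782 genes (994 rose, 788 fell) and the authors' test 2229, with 1605 in both. In intronic reads, 909 of 10215 genes were at least 2-fold apart and limma called 665. limma called 535 exonic genes without exonic KO library 1 and 597 without exonic KO library 2, and 223 and 162 intronic genes without intronic KO library 1 and 2, which are numbered apart from the exonic libraries; with a term for library order, a hint from the data only, it called 5052 and 3112. The direction depended on single libraries and on the minimum: by size it was 742 higher and 654 lower without exonic WT library 2 and 457 and 402 at a minimum mean of 200, and by limma 258 and 339 without exonic KO library 2 and 268 and 267 without exonic KO library 1. Each genotype is a single clone, so these differences are between 2 clones.

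Exonic and intronic changes went together across genes in Dicer KO cells, with r = 0.935 and rho = 0.864 over 9402 genes, which are not independent replicates. Nr6a1 stood out by an exonic rise that exceeded the intronic change by 3.32 ± 0.14, and so did Hmga2, a chromatin protein of embryonic cells and let-7 target, by 2.76 ± 0.13. For Prtg and Kng2 the excess was 2.14 ± 0.14 and 2.13 ± 0.38. Rora, a nuclear receptor, fell less in exonic than in intronic reads, at −1.70 against −4.73, a difference of 3.03 ± 0.30. In the other direction stood Plce1 at −2.83 ± 0.14, the protease gene Ctsc at −1.71 ± 0.14, Actg2 at −1.65 ± 0.12, Ephb2 at −1.22 ± 0.15 and Mcts1 at −1.06 ± 0.15, and all 10 passed limma on the difference. In total, limma called 314 genes, 235 with more exonic than intronic change and 79 with less. By size, 116 genes differed by at least 1 on the log2 scale, 74 higher and 42 lower. With means of at least 200 in both kinds of reads, limma called 494 genes and the size rule 43; with a term for library order, a hint from the data only, limma called 881, 630 with more and 251 with less.

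**Figure D2:**
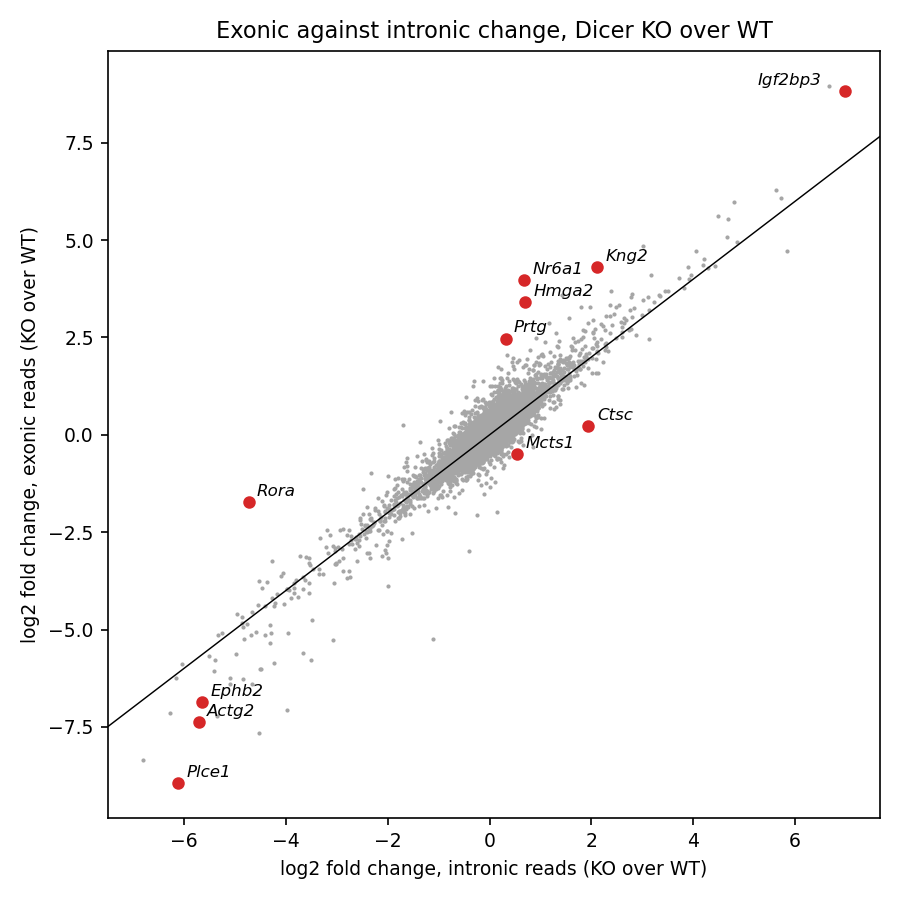
Log2 fold change of Dicer KO over Dicer WT in intronic reads (x axis) and exonic reads (y axis), 1 grey point for each of 9402 genes, from means of 2 libraries per group; red points are labelled genes and the line marks equal change. Most genes lie along the line (r = 0.935 across genes), with Nr6a1 and Hmga2 above it and Plce1 below it.

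Genes with let-7 seed sites in their 3′ untranslated regions were higher in exonic than intronic reads of Dicer KO cells. The 1007 genes with a site had a median difference of 0.12, against 0.02 in genes without, which is 0.06 above matched random lists. Of 22 microRNA families used in stromal cells, 18 lay above the central 95% of matched lists in this difference, 11 did so in exonic reads alone and 4 in intronic reads alone. Of 6 families of other tissues, those of miR-1, miR-122 and miR-200b (3) did so in the difference, 0 in exonic and 0 in intronic reads. With 8-mer sites 18 stromal families and 1 of the others, that of miR-1, did so in the difference, with miR-122 at percentile 92.4 and miR-200b at 87.2; with means of at least 200 these counts were 16 and 2. With 7-mer sites the stromal families that did not were those of miR-221, miR-22, miR-24 and miR-31 (4). The median excess over matched lists was 0.03 for stromal families and 0.02 for the others, and the difference between these classes was not tested. Families share target genes, and the percentiles describe these libraries only.

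**Figure D3:**
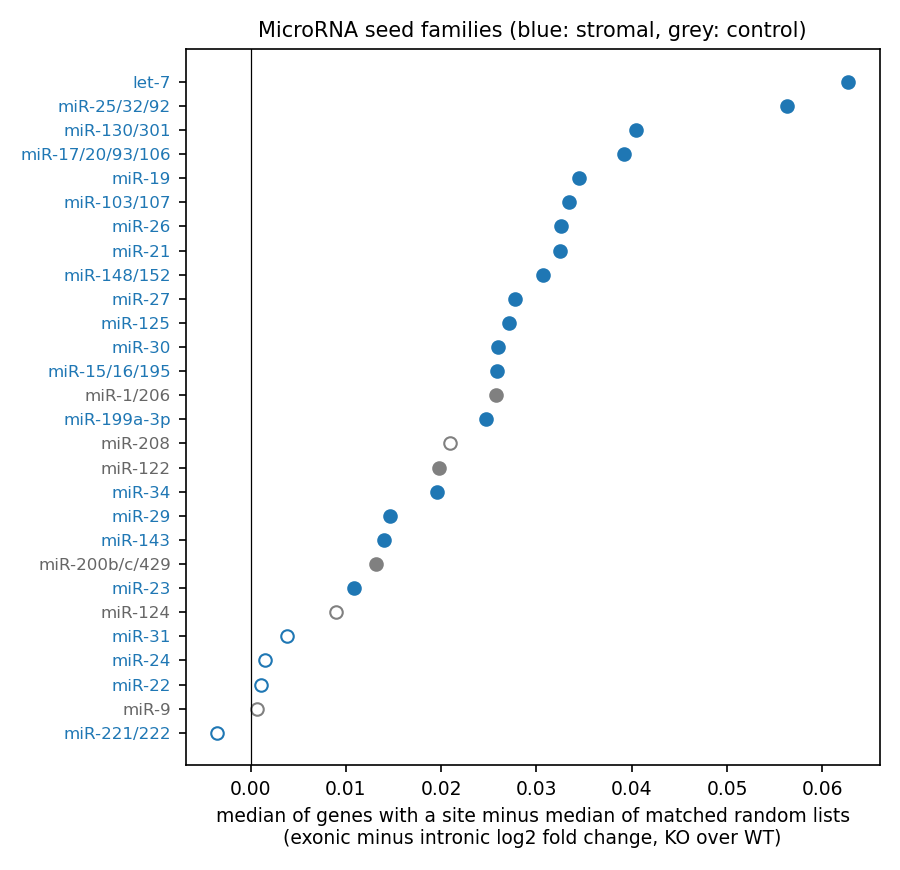
Median exonic minus intronic log2 fold change of genes with a seed site, less the median of matched random lists (x axis, log2), for each microRNA family (y axis); blue points are stromal families, grey points families of other tissues, and filled points lie above the central 95% of matched lists. With these 7-mer sites the let-7 family is highest at 0.06; with 8-mer sites the family of miR-25 stood at 0.13, above let-7 at 0.10.

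The comparison of Pbx3 with vector asks what raised Pbx3 does in WT cells. Among the genes with the lowest exonic values were Cbln1, a synaptic organiser, at −3.37 ± 0.56, Igfbp4, which binds insulin-like growth factors, at −3.32 ± 0.63, the Wnt inhibitor Sfrp1 at −2.20 ± 0.40, the protease Adamts9 at −2.11 ± 0.61, the glutathione transferase Mgst1 at −2.07 ± 0.40, the BMP inhibitor Chrdl1 at −1.99 ± 0.32 and the glutamate transporter Slc1a3 at −1.93 ± 0.17. None of these passed limma over all genes. The authors' adjusted p was 4.89e-05 for Chrdl1, 3.74e-06 for Slc1a3 and 2.1e-05 for Fabp4, which stood at −1.72 ± 0.19. Among the highest values, Eps8, an actin regulator, stood at 1.46 ± 0.17 (the authors' adjusted p = 0.00507), the zinc finger gene Zfp462 at 1.25 ± 0.26, the receptor Cxadr at 1.17 ± 0.31 and Nov, a matricellular protein, at 1.62 ± 1.42. Intronic values were −2.05 ± 0.25 for Chrdl1, −2.03 ± 0.26 for the ephrin Efna5, −1.91 ± 0.17 for Slc1a3 and −1.85 ± 0.23 for Sncaip.

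Osteoblast markers were lower in Pbx3 cells, with a median of −0.78 at percentile 0 of random lists. Of 12 measured, 0 passed limma and 0 adjusted over the list alone, 4 were lower at an unadjusted p under 0.05, and the authors' test called 0. Ibsp, a bone matrix protein, stood at −1.87 ± 0.64, Sp7 at −1.72 ± 0.40, Pth1r at −1.48 ± 0.38 and the phosphatase Alpl at −1.07 ± 0.58. The list is among those that differed between the 2 libraries of every group. Of 12 inflammatory and NF-kB genes, 0 passed limma over all genes, 3 were lower at an unadjusted p under 0.05, 1 was lower in the authors' test, and 3 were lower adjusted over the list alone: Ccl7 at −1.85 ± 0.38, Ccl2 at −1.53 ± 0.19 and Cxcl1 at −0.96 ± 0.24. This list's median of −0.15, at percentile 0.65, was −0.08 at percentile 10.1 with a minimum mean of 200. The 33 matrix genes had a median of 0.19 at percentile 100, with 0 passing limma or adjusted over the list alone, 3 higher at an unadjusted p under 0.05 and 0 in the authors' test. Between the 2 libraries of a group, the matrix list differed by a median of −0.292 in vector and −0.209 in Pbx3. Of 11 PBX, MEIS and PREP cofactor genes, 1, Pbx3 itself, rose, also adjusted over the list alone.

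By size, 95 of 9826 genes were at least 2-fold apart in exonic reads of Pbx3 cells (31 higher, 64 lower), 80 of them without overlap of libraries. Over all genes the share without overlap was 24.7%, below the 33.3% of libraries that differ only at random. limma called 1 gene, Pbx3, with 233 at an unadjusted p under 0.05 and 15 in the authors' test. In intronic reads 70 of 8557 genes were at least 2-fold apart, while limma called 0, with 248 at an unadjusted p under 0.05 and 24 in the authors' test. limma called 7 genes without vector library 1, 19 without vector library 2, 4 without Pbx3 library 1 and 8 without Pbx3 library 2; in intronic reads these were 8, 17, 24 and 45, and with a term for library order, a hint from the data only, it called 596 exonic and 623 intronic genes. The direction by size depended on single libraries: it was 140 higher and 42 lower without vector library 1 and 74 and 65 without Pbx3 library 1. The size rule gave 182, 151 and 266 genes without vector library 1, vector library 2 and Pbx3 library 2, and in intronic reads 109 and 162 without vector library 2 and Pbx3 library 2. Exonic and intronic changes correlated at r = 0.782 and rho = 0.670 across 7973 genes, which are not independent replicates, and limma on their difference called Pbx3 alone (1 gene, 218 at an unadjusted p under 0.05).

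The comparison of Sox9 with vector asks what the transfected Sox9 does in WT cells. Cartilage genes rose: Hapln1, which links aggrecan to hyaluronan, by 9.56 ± 0.32, the cartilage collagens Col11a1 and Col2a1 by 5.72 ± 0.33 and 4.76 ± 0.21, and in intronic reads Sox6, a partner of Sox9, by 4.47 ± 0.28. Acan, the aggrecan gene, rose from 1 read to 858, a ratio with a 95% counting interval of 215 to 47509, and Lect1, the chondromodulin gene, from 1 to 378, with an interval of 94.4 to 20961. C1qtnf3 rose from 2 reads to 1212, with an interval of 234 to 7015. Of 14 SOX9 and cartilage genes, 7 rose and 7 did not pass limma, with 12 higher adjusted over the list alone and a median of 2.13 at percentile 100. Members almost without reads in vector, such as Acan and Lect1, passed the minimum mean only through Sox9 cells. In Pbx3 cells 10 members were measured and in Tead4 cells 9. The median and its percentile are therefore raised in part by the filter. In intronic reads 6 of 11 rose, with 10 higher adjusted over the list alone.

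Genes outside the cartilage list rose in Sox9 cells as well. Igfbp5 rose by 7.07 ± 0.95, Edil3, an integrin ligand, by 3.93 ± 0.25, the signalling regulator Rgs17 by 3.03 ± 0.24, Itm2a by 2.96 ± 0.37, Apba1 by 2.96 ± 0.23 and Igf2bp2 by 2.48 ± 0.26. Of 3 measured neuronal and glial markers, 1 rose, Stmn2, a tubulin-binding protein of neurons, at 5.75 ± 0.48, with 2 higher adjusted over the list alone. The further gene, the calcium-binding protein S100b, stood at 4.93 ± 0.90. Only 1 member of this list was measured in Pbx3 cells and 1 in Tead4 cells, so the others can have entered through Sox9 cells. Of 33 matrix genes, 1 rose, Col5a1, with 9 higher and 1 lower (Fbln2) adjusted over the list alone and a median of 0.37 at percentile 100. Col3a1 stood at 2.54 ± 0.41 and fibronectin, Fn1, at 1.44 ± 0.22. Between the 2 libraries of a group, the matrix list differed by a median of −0.292 in vector and −0.417 in Sox9. Of 23 miR-29 targets, many of them collagens, the same Col5a1 rose (1), with 11 higher adjusted over the list alone and a median of 0.57 at percentile 100. Col5a1 and Fbln2 were chosen after their values were seen.

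Fhl1, a LIM protein of muscle, and Hbegf, a ligand of the EGF receptor, fell in Sox9 cells, at −1.88 ± 0.15 and −1.80 ± 0.20. In intronic reads the YAP target Ankrd1 fell, at −1.69 ± 0.25, as did the early response gene Klf6 at −1.65 ± 0.19, the matricellular gene Ctgf at −2.30 ± 0.35 and the kinase Sgk1 at −1.75 ± 0.35. Exonic values of Ctgf and Sgk1 were −1.81 ± 0.37 and −1.39 ± 0.28 and did not pass. Of 29 TEAD-YAP targets, 0 passed limma in exonic reads (3 higher and 6 lower at an unadjusted p under 0.05, 1 lower in the authors' test), and 4, among them Ctgf, Ankrd1 and Edn1, were lower adjusted over the list alone. In intronic reads 4 of 26 fell and 0 rose, with 2 higher and 8 lower adjusted over the list alone (3 higher and 9 lower at an unadjusted p under 0.05, 0 higher and 5 lower in the authors' test). Of 15 interferon-stimulated genes, 0 passed limma, 7 were lower at an unadjusted p under 0.05, 1 was lower in the authors' test and 2, Ifih1 and Parp14, were lower adjusted over the list alone, with a median of −0.38 at percentile 0.02; the median was −0.21 at percentile 5.52 with a minimum mean of 200. Ribosomal protein genes had a median of −0.24 at percentile 0.05, with 0 of 38 passing limma or adjusted over the list alone, 3 lower at an unadjusted p under 0.05 and 0 in the authors' test. The ribosomal list is among those that differed between the 2 libraries of every group.

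By size, 241 of 9698 genes were at least 2-fold apart in exonic reads of Sox9 cells (173 higher, 68 lower), 228 of them without overlap of libraries. Over all genes this share was 45.3%, where libraries that differ only at random would give 33.3%. limma called 53 genes (44 rose, 9 fell), the authors' test 186, and 51 were in both. In intronic reads 190 of 8361 genes were at least 2-fold apart and limma called 166 (121 rose, 45 fell). The excess of higher genes depended on the fit. With a term for library order the limma split was 942 higher and 848 lower in exonic reads and 795 and 763 in intronic reads. limma called 1271 genes without vector library 1, 252 without vector library 2 and 146 without Sox9 library 2, and 389 intronic genes without vector library 1; with a term for library order, a hint from the data only, it called 1790 exonic and 1558 intronic genes. The size rule gave 535 genes without vector library 1 and 362 without Sox9 library 2, and 326 intronic genes without vector library 1; without Sox9 library 1 the exonic split was 130 higher and 116 lower. Exonic and intronic changes correlated at r = 0.832 and rho = 0.727 across 7784 genes, which are not independent replicates. By size 21 genes differed between the 2 kinds of reads, and limma called 1, the adhesion gene Chl1, chosen after its values were seen; with a pseudocount of 8 or means of at least 200 it called 0 (960 and 637 at an unadjusted p under 0.05). With means of at least 200 the size rule gave 6 genes.

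The comparison of Tead4 with vector asks what raised Tead4 does in WT cells. Crabp1, which binds retinoic acid, rose by 5.13 ± 0.38, Dock8, an activator of small GTPases, by 3.55 ± 0.34, Igf2bp2 by 2.88 ± 0.27, the water channel Aqp1 by 1.78 ± 0.15 and fibrillin, Fbn1, by 1.45 ± 0.14. Chrdl1 and Fabp4 fell, at −3.62 ± 0.17 and −1.42 ± 0.13. In intronic reads Fgf12 and Lphn3, genes of neurons, rose by 3.38 ± 0.27 and 2.63 ± 0.21 and Sncaip fell by 5.06 ± 0.29. Genes with large values that did not pass in exonic reads were Igfbp4 at −5.20 ± 0.62, Sfrp1 at −2.84 ± 0.44, the matrix gene Postn at −2.42 ± 0.42, Cldn1, a tight junction protein, at 2.31 ± 0.33, the lactate transporter Slc16a3 at 2.15 ± 0.23 and Hmga2 at 2.07 ± 0.28. In intronic reads Hmga2 rose by 2.27 ± 0.29, Alcam, an adhesion molecule, rose by 1.78 ± 0.33 and Adamts9 fell by 4.13 ± 0.58.

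Osteoblast markers were lower in Tead4 cells, with a median of −0.66 at percentile 0. Of 11 measured, 0 passed limma in exonic reads over all genes, 4 were lower at an unadjusted p under 0.05, the authors' test called 3 lower and 4 were lower adjusted over the list alone: Pth1r at −4.23 ± 0.65, Alpl at −3.26 ± 0.68, Sp7 at −2.24 ± 0.41 and Bmp4 at −1.03 ± 0.16. In intronic reads 3 of 10 fell, Pth1r, Alpl and Sp7, with 4 lower and 1 higher adjusted over the list alone. The list is 1 of those that differed between the 2 libraries of every group. Of 9 cartilage genes, 0 passed limma, 1 was higher and 6 lower at an unadjusted p under 0.05, the authors' test called 1 higher and 2 lower, and 1 was higher and 6 lower adjusted over the list alone; Col27a1 stood at −2.27 and Col2a1 at −1.39, with Col11a1 at 1.61. The list median of −1.15, at percentile 0, was −0.01 at percentile 46.6 with a minimum mean of 200. Between the 2 libraries of a group, the cartilage list differed by a median of −0.634 in vector and −0.402 in Tead4. For the matrix list these were −0.292 and −0.250. Of 33 matrix genes, 1 rose, Fbn1, with 1 higher and 5 lower adjusted over the list alone; Mmp2 stood at −1.78 and Tnc at −1.68 ± 0.30, and the median was −0.32 at percentile 0. Postn, Fbln5 and Lox were the other 3 lower members, the last 2 chosen after their values were seen.

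TEAD-YAP targets went both ways in Tead4 cells. Of 29 measured, 0 passed limma in exonic reads, 3 were higher and 8 lower at an unadjusted p under 0.05, the authors' test called 1 higher and 1 lower, and 1 higher (Dock5) and 3 lower held adjusted over the list alone, with a median of −0.09 at percentile 7.84. The intronic median was −0.18 at percentile 0.35. Ccdc80, Ctgf and Edn1 stood at −1.59, −1.25 and −1.23 in exonic reads and fell in intronic reads, where 1 of 26 members rose and 4 fell, with the same counts adjusted over the list alone; Dock5, the member that rose there, was chosen after its values were seen. Of 18 TEAD and Hippo pathway genes, 1 rose, Tead4 itself, with 2 higher adjusted over the list alone; the further gene, Tead3, stood at 1.33 ± 0.22. Of 18 stromal markers, 0 passed limma, 7 were higher and 1 lower at an unadjusted p under 0.05, the authors' test called 1 higher, and 5 were higher adjusted over the list alone, with a median of 0.44 at percentile 100; these were Alcam and, chosen after their values were seen, Nt5e, Prrx2, Twist2 and Nes. Cholesterol synthesis genes had a median of 0.55 at percentile 100, with 0 of 20 passing limma or adjusted over the list alone, 3 higher at an unadjusted p under 0.05 and 0 in the authors' test. The stromal and cholesterol lists are among those that differed between the 2 libraries of every group.

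By size, 318 of 9796 genes were at least 2-fold apart in exonic reads of Tead4 cells (136 higher, 182 lower), 306 of them without overlap of libraries. Over all genes this share was 49.2%, where libraries that differ only at random would give 33.3%. limma called 14 genes (8 rose, 6 fell), all 14 also in the authors' test, which called 358. In intronic reads 208 of 8582 genes were at least 2-fold apart and limma called 138 (65 rose, 73 fell). At a minimum mean of 200, limma called 50 intronic genes, with the direction turned to 30 higher and 20 lower. limma called 2375 genes without vector library 1, 1136 without vector library 2, 5 without Tead4 library 1 and 36 without Tead4 library 2; in intronic reads it called 900, 361 and 49 without vector library 1, vector library 2 and Tead4 library 1. With a term for library order, a hint from the data only, it called 857 exonic and 1389 intronic genes, and in a joint fit of the 8 transfected libraries 87 exonic genes, with the direction turned to 35 higher and 52 lower. The size rule gave 517 genes without vector library 1, where the direction turned to 335 higher and 182 lower; without vector library 2 it was 101 and 239. Exonic and intronic changes correlated at r = 0.908 and rho = 0.836 across 7984 genes, which are not independent replicates, and limma on their difference called 2 genes, Tead4 and Dock8 (460 at an unadjusted p under 0.05), but 0 with a term for library order (499 at an unadjusted p under 0.05).

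**Figure D4:**
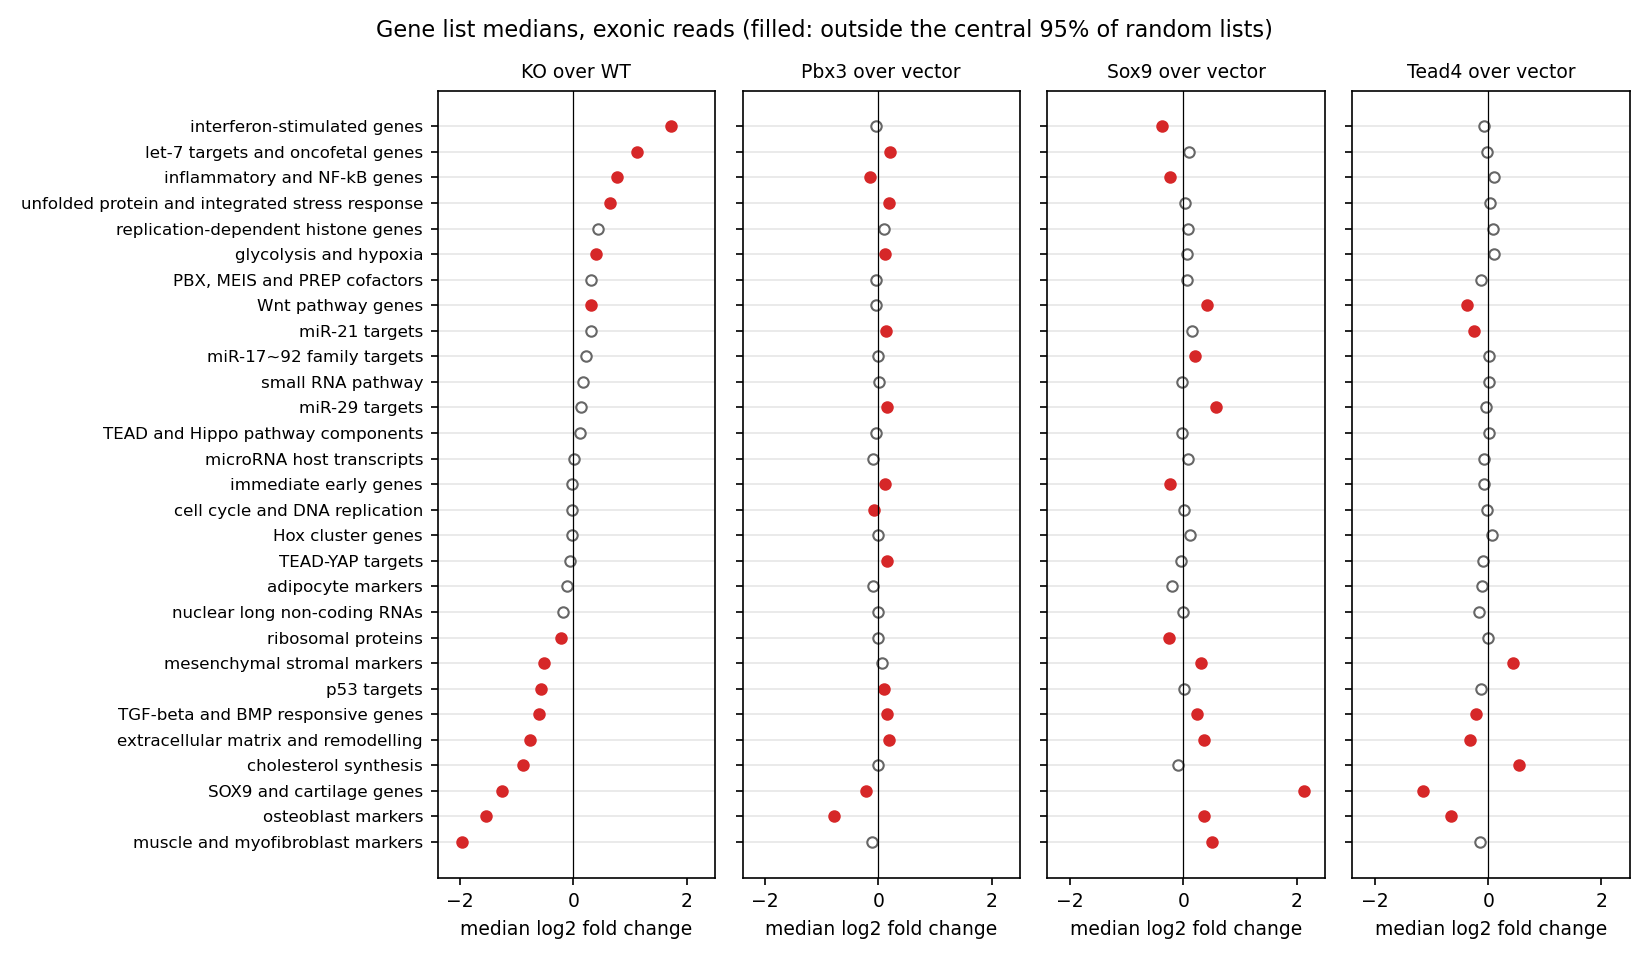
Median exonic log2 fold change of the measured members of each gene list (x axis) for the 4 comparisons (panels), lists ordered by their Dicer KO median (y axis); filled red points lie outside the central 95% of matched random lists. Interferon-stimulated genes and let-7 targets have the highest medians in Dicer KO, while cartilage genes have the highest median drawn in Sox9 cells and the lowest in Tead4 cells. Lists without a median in Dicer KO are not drawn, such as neuronal and glial markers, at 4.425 over 3 genes in Sox9 cells. Medians in Sox9 cells include genes that passed the minimum mean only through these cells, such as Acan among the cartilage genes.

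Of 29 lists measured in exonic reads, 6 lay above and 9 below the central 95% of random lists in Dicer KO, 10 and 4 in Pbx3, and 2 and 6 in Tead4, where chance gives 1.45 outside in all. In Sox9 cells 10 lay above and 4 below of 30 lists, where chance gives 1.5. These chance values take the genes of a list as independent, yet whole lists moved together between the 2 libraries of every group, so unchanged groups can exceed them too. At a minimum mean of 200, the interferon, inflammatory and immediate early lists of Sox9 cells moved inside and miR-21 targets outside. In Pbx3 cells the let-7, p53, immediate early, stress response and inflammatory lists moved inside and the adipocyte list outside. For Tead4, miR-21 targets and cartilage genes moved inside and the adipocyte and muscle lists outside. For Dicer KO the Wnt list moved inside and miR-29 targets outside.

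The series sets 3 factors expressed in WT cells beside the loss of Dicer, and the exonic changes were set side by side across 9585 genes, which are not independent replicates. Dicer KO and Tead4 changes correlated at r = 0.263 and rho = 0.179, Dicer KO and Pbx3 at r = 0.224 and rho = 0.163, and Dicer KO and Sox9 at r = 0.024 and rho = 0.094. Of genes at least 2-fold apart in both, 87 were lower in Dicer KO and in Tead4 cells, where 9.52 would be if the comparisons were independent, and 30 were higher, against 3.80, while 39 went opposite ways, against 12.2. For Pbx3, 41 were lower in both against 3.3, 6 higher against 0.509 and 4 opposite against 3.12. For Sox9, 28 were lower in both against 3.62, 22 higher against 4.19 and 43 opposite against 8.35. Pbx3, Sox9 and Tead4 share the vector libraries, which by itself makes their changes correlate. Pbx3 and Tead4 correlated at r = 0.389, below the r = 0.508 simulated for unchanged libraries against shared vector libraries, with a covariance of 0.0463 against 0.00361. Sox9 and Tead4 correlated at r = 0.303, below 0.461, with a covariance of 0.050 against 0.00361, and Pbx3 and Sox9 at r = 0.20, below 0.464, with a covariance of 0.0212 against 0.00362. The simulated values cover counting error only and the spread between the vector libraries is larger, so these values do not show a response shared by the factors.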

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

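limma, leaving out single libraries, the term for library order and the joint fit of the 8 transfected libraries were chosen only after the data were seen; all other settings were fixed in advance. Of the settings tried on 2-fold counts, 55 stayed within 1.5 times the reported count and 41 did not; for limma counts these were 30 and 44. List medians stayed inside or stayed outside the central 95% of random lists in 331 settings, moved outside in 5 and moved inside in 11; some medians near 0 that stayed inside changed sign. Seed medians did so in 49, 1 and 5, and 1 outside it reversed. Values per result come below in the order Dicer KO, Pbx3, Sox9, Tead4, and where they changed the cause was not tested, except that a minimum of 200 leaves fewer genes. Where a library is left out, the lone library of its group is assumed to vary like the other group; this was not run for the difference of exonic and intronic change. No paired analysis was possible because the labels give no replicate numbers for the recovered libraries, and the term for library order below is a hint from the data only.

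With no minimum mean, the 2-fold counts were 3071, 851, 1273 and 1362 in exonic and 2842, 1148, 1558 and 1551 in intronic reads. With a minimum of 200 they were 859, 32, 94 and 130, and 509, 19, 84 and 68, over fewer genes. The exact binomial test of summed reads, which compares libraries and not conditions, called 8840, 3949, 5588 and 5833, and 7170, 2061, 3996 and 3991. The authors' test called 2229 exonic genes in Dicer KO and 15 exonic and 24 intronic genes in Pbx3. limma called 1, 53 and 14 exonic genes in Pbx3, Sox9 and Tead4, and 0 and 138 intronic genes in Pbx3 and Tead4 (248 and 1327 at an unadjusted p under 0.05; 24 and 251 in the authors' test). Leaving out 1 library gave 139 to 266 exonic and 91 to 162 intronic genes in Pbx3, 220 to 535 and 198 to 326 in Sox9, and 283 to 517 exonic genes in Tead4. Columns rescaled to the same total, centred medians and a pseudocount of 8 left the 2-fold counts within 1.5 times.

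For limma, leaving out 1 library gave 535 to 1908, 4 to 19, 73 to 1271 and 5 to 2375 exonic genes, and 162 to 955, 8 to 45, 114 to 389 and 49 to 900 intronic genes. A term for library order gave 5052, 596, 1790 and 857 exonic and 3112, 623, 1558 and 1389 intronic genes. On the difference of exonic and intronic change it gave 881 in Dicer KO, 2 in Sox9 and 0 in Tead4 (499 at an unadjusted p under 0.05 for Tead4). The joint fit gave 3 exonic and 10 intronic genes in Pbx3 and 87 exonic genes in Tead4. A minimum of 200 gave 23 exonic genes in Sox9, 9 exonic and 50 intronic in Tead4 and 377 intronic in Dicer KO; on the difference it gave 494 in Dicer KO and 0 in Sox9, where a pseudocount of 8 also gave 0 (637 and 960 at an unadjusted p under 0.05). By size, the difference passed in 43, 6 and 2 genes in Dicer KO, Sox9 and Tead4 at a minimum of 200. Tead4 itself stood at 6.96 with a pseudocount of 8. At a minimum of 200, Pbx3 and Sox9 changes correlated across genes at r = 0.140 in exonic and −0.0199 in intronic reads, the latter with the sign reversed, and Pbx3 and Tead4 at 0.335 in intronic reads. With 8-mer sites the miR-143 excess was reversed, at −0.00415.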

Other observations

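Tests chosen only after the result was seen were those on endogenous transcription of the transfected genes, on imbalance between libraries and on a shared response for the genes lower under all 3 factors, and on depth and on a shared culture state for the difference between libraries; the others were chosen before.

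Of 11 PBX, MEIS and PREP cofactor genes, 3 rose and 2 fell in Dicer KO cells by limma, with the same counts adjusted over the list alone: Pknox2 rose by 0.99 ± 0.15, Pbx2 by 0.97 ± 0.21 and Pbx3 by 0.83 ± 0.15, while Meis2, a homeodomain partner, stood at −2.55 ± 0.26 and Pknox1 at −0.89 ± 0.17. Of 16 Hox genes, Hoxa9 rose by 1.12 ± 0.18 and Hoxc13 fell by 1.71 ± 0.37 (1 and 1, also adjusted over the list alone). Of 18 TEAD and Hippo pathway genes, Tead4 and Wwc1 rose and Tead3 and Vgll3 fell (2 and 2 by limma, 3 and 2 adjusted over the list alone), the last pair at −2.07 ± 0.30 and −2.25 ± 0.37. Among 23 targets of the miR-17~92 family, 3 rose and 2 fell, with the same counts adjusted over the list alone: the cyclin Ccnd1 rose by 1.88 ± 0.21, Map3k2 and Phlpp2, chosen after their values were seen, also rose, and Bambi and Cdkn1a stood at −2.44 ± 0.26 and −1.13 ± 0.22. Among 14 miR-21 targets, 3 rose and 1 fell (5 and 2 adjusted over the list alone), with Tgfbi at 1.99 ± 0.42 and the protease inhibitor Reck at 1.40 ± 0.25; Smad7 and Tpm1, the further pair, were chosen after their values were seen. Of 43 cell cycle genes 1 fell by limma, the centromere gene Cenpa, by 0.87 ± 0.18, and 0 adjusted over the list alone (1 in the authors' test).

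The intronic reads of the transfected genes were higher beside their exonic reads, Pbx3 from 2845 to 10052 and Tead4 from 75 to 1557 over both libraries. A fixed share of exonic reads counted as intronic for every gene would forbid lower ratios in other genes. Of 2299 genes with many exons and reads, 78 (3.39%) had an intron to exon ratio under 5.50%, below the bound of 5% of genes. By that bound a fixed share was not excluded. These 78 genes argue against a share of 11% in every gene, which the smallest gain would need. Such counting at a smaller share may still carry the intronic gain in part. Transcription of the endogenous genes cannot be told apart from it, since gene totals hold no positions; the intronic gain was 11% of the exonic gain for Pbx3, 12.2% for Tead4 and 22.7% for Sox9.

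Under all 3 factors, 14 genes were at least 2-fold lower, where 0.0082 would be if the comparisons were independent, which they are not, since they share vector libraries. The set was formed after the values were seen and includes Igfbp4, Adamts9, Sfrp1, Il1rn, Islr, Mgst1 and Sncaip, with a median drop of −2.44. Of the 14, 10 were also at least 2-fold lower in Dicer KO, against 708 of all 10706 genes. The set was picked for large drops in these data, so this overlap does not show a shared response. Vector libraries did not stand above untransfected WT for the set: the median of vector over WT was −0.441 (quartiles −0.88 to 0.12), below the bound of 1.22. This cannot exclude vector libraries that stand too high beside the factor libraries, because vector and untransfected WT cells also differ by transfection. Imbalance of libraries along the shared genes could not be excluded, although the weakest median drop between libraries at the same end was −1.53. The genes were chosen for lower group means, which largely set the drops at the 2 ends. Libraries at the same end also need not lie equally far along. Islr, Adamts9 and Dpep1 of the set were among the genes that differed most between libraries, at means of −2.11, −2.09 and −1.91. A response shared by the 3 factors may stand behind these 14.0 genes. It cannot be told apart from such imbalance or from vector libraries that stand apart. Nor can it be told apart from an effect of any insert, since no group carries an unrelated insert.

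The 2 libraries of every group differed along the same genes, with r of 0.371 to 0.831 across 8073 genes over the 15 pairs of groups (genes are not independent replicates), and 30.8% of genes differed the same way in all 6 groups; the order of libraries was set from these same genes, so no chance value is given. Depth was excluded as the cause, since the deeper exonic library lay at the same end in only 4.0 of 6 groups. GC content and transcript length were excluded as the whole cause, with rho of −0.229 and −0.02 across genes. A culture state or day shared across groups may stand behind it: the median difference of 19 cholesterol synthesis genes was −1.22 over the groups, while the labels give no day, so this cannot be told apart from other handling.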
